A study of Homo sapiens with 6 samples.

How the data were processed

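RNA was measured by sequencing of polyA-selected libraries from C4-2 cells, 3 treated with IPI-9119 at 100 nM and 3 with 0.1% DMSO, for 6 days. The deposited values are a signal, gene counts that the authors divided by a size factor for each library, as the values themselves show. Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2, DESeq2 and the build GRCh38 are named, with no role or order, per the submitters' processing notes. The annotation release and the strand setting of the counting were not given in the sources used here. The deposited table held 14456 genes, none duplicated, of which 14409 were in GENCODE 29 and 14355 had a symbol. The lowest total of a gene in it was 61 reads. All columns were mapped to samples by name.

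Low values in each library were whole multiples of the value of a single read, between 0.894 and 1.10, which gave the read counts back. All values (100%) came out whole within 0.01 read. The recovered totals ran from 19090749 to 23448035 reads per library. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 2.29 to 9.57), so each was counted as a separate sample. Longer and more abundant transcripts are measured with more reads and thus more precisely.

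The main test was limma 3.58.1 in R 4.3.3, with trend and robust moderation, on log2(value + 1), comparing all IPI-9119 with all DMSO libraries. Fold changes are on that scale, which understates the change of low genes. Genes with a mean value of at least 10 were tested, which removed 19. Benjamini-Hochberg adjusted p-values under 0.05 were called. Tests of single genes were two-sided. Count tests on the recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, were alternatives: limma called 9061 genes, edgeR 9081 and DESeq2 8460, and 8988 calls were shared by limma and edgeR in the same direction. Gene positions, exonic lengths and GC content came from GENCODE 29 on GRCh38. Exonic length was that of all annotated exons of a gene merged, which can exceed the length of any single transcript. GC content was that of the longest annotated transcript. Where transcript length is named below, exonic length is meant.

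Before the data were examined, 30 gene lists with 688 genes were fixed, among them markers of other cell types. The 27 lists with at least 4 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The version with an estimated correlation rests on the 4 residual degrees of freedom. Calls were lost with it even where the estimate lay below the preset value, as for interferon-stimulated genes (-0.023). A call lost this way thus need not reflect correlation among the members. For other lost calls the estimate lay far above the preset value, as for nuclear oxidative phosphorylation (0.743) and cytosolic ribosomal proteins (0.912). Correlation may count there. The fry test was run too, directional and mixed, which does not compare a list with other genes. Genes named in the text followed a rule fixed at the same time. They are FASN, KLK3 and MKI67, the 8 largest rises and 8 largest falls among called genes with a mean of at least 100, non-overlapping libraries and a symbol of a named gene, and the 3 called members of each list with the largest change. Where members went both ways and these 3 did not, the largest change the other way was added, and a list with no called member gave the member with the smallest p. Some results under this rule are not reported here.

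Alternatives were a replicate block, pseudocounts of 0.5 and 8, no filter, a mean of at least 50, and TMM and quantile scaling. Further ones were no trend and no robust moderation together (for list tests, no trend), the count tests, and leaving out each library in turn. A correction for transcript length and GC content was chosen after seeing the data. It subtracted, for each library, a spline fit (4 degrees of freedom each, with interaction) of the log2 deviation from the gene mean on log2 exonic length and GC percent. Of the genes tested 99.6% had both values. The tests were tested on simulated counts of the IPI-9119 against DMSO comparison over 14437 genes. There limma found 98 of 100 genes changed 2-fold and 84 of 100 changed 1.5-fold, with 23 unchanged genes called. For edgeR these were 98, 84 and 26, and for DESeq2 98, 83 and 14. The changed genes counted here had a mean of at least 50, so these rates do not cover lower genes. They were also few, whereas 62.8% of genes were called in the data. The camera step found the 1 changed list among 27 and called 0 unchanged lists. Genes were simulated independently of each other, so this cannot show how often correlated lists are called falsely. Over 14386 genes with a simulated length and GC trend, calls fell from 3367 to 234 after the correction, against 232 without a trend. That trend was linear in log2 length and GC content, a shape the spline can fit, and few genes were changed. The simulation thus cannot show how the correction fares on the trend of these data, or whether corrected values of single genes are right. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.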

Results

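Polyadenylated RNA was sequenced from C4-2 cells, a line of castration-resistant prostate cancer derived from LNCaP. The cells were grown in serum-containing medium and treated for 6 days with 100 nM IPI-9119, an inhibitor of the enzyme fatty acid synthase, or with 0.1% DMSO. Each group held 3 libraries. The recovered read totals were 23448035, 21952620 and 22910520 in the DMSO libraries and 20422882, 19291069 and 19090749 in the IPI-9119 libraries, a ratio of means of 0.861. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

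The comparison asked how the transcriptome of these cells differed after 6 days of fatty acid synthase inhibition. Genes of sterol synthesis, DNA replication and mitosis were higher in the IPI-9119 libraries, and androgen-induced genes and genes of the amino acid response were lower. At the preset correlation, splits of the libraries that mix the groups also gave 11 to 16 lists past camera, against 16 for the real groups. Each such split still holds part of the group difference. With an estimated correlation the list calls of S phase, mitosis and the amino acid response held (adjusted p = 0.0212 each). Those of sterol synthesis and androgen-induced genes were lost (adjusted p = 0.0532 each). That version also has fewer degrees of freedom, so a lost call need not come from correlation among members. Of 14437 genes tested with limma, 4522 were higher and 4539 lower at an adjusted p under 0.05, and 5376 were not past the threshold. At least a 2-fold difference was found for 1143 higher and 1338 lower genes. The median log2 fold change over all genes was 0.0017. The libraries of the groups did not overlap for 4907 genes that were higher and 4889 that were lower, 67.9% of the genes tested against 10% by chance. The first principal component, which separated the groups, held 83.0% of the variance. The groups cannot be told apart from any difference in library batch, since the labels give no batch.

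FASN, which encodes the target enzyme, did not pass the test. Its gene (ENSG00000169710, chromosome 17, 82078333 to 82098332, minus strand, GRCh38, GENCODE 29) gave 13182, 15941 and 15107 normalised counts in the DMSO libraries and 9365, 13284 and 13511 in the IPI-9119 libraries. The means were 14743 ± 1415 and 12053 ± 2331 (SD, n = 3), a log2 fold change of -0.31 (SE 0.15, adjusted p 0.112). Without IPI-9119 replicate 3 the value was -0.40 and past the threshold (adjusted p 0.0225), and without IPI-9119 replicate 1, the lowest library, it was -0.13 (adjusted p 0.0773). After a correction for transcript length and GC content it was 0.84 (adjusted p 2.1e-08). Adjusted p-values of FASN over the alternatives ran from 2.1e-08 to 0.298.

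**Figure D1:**
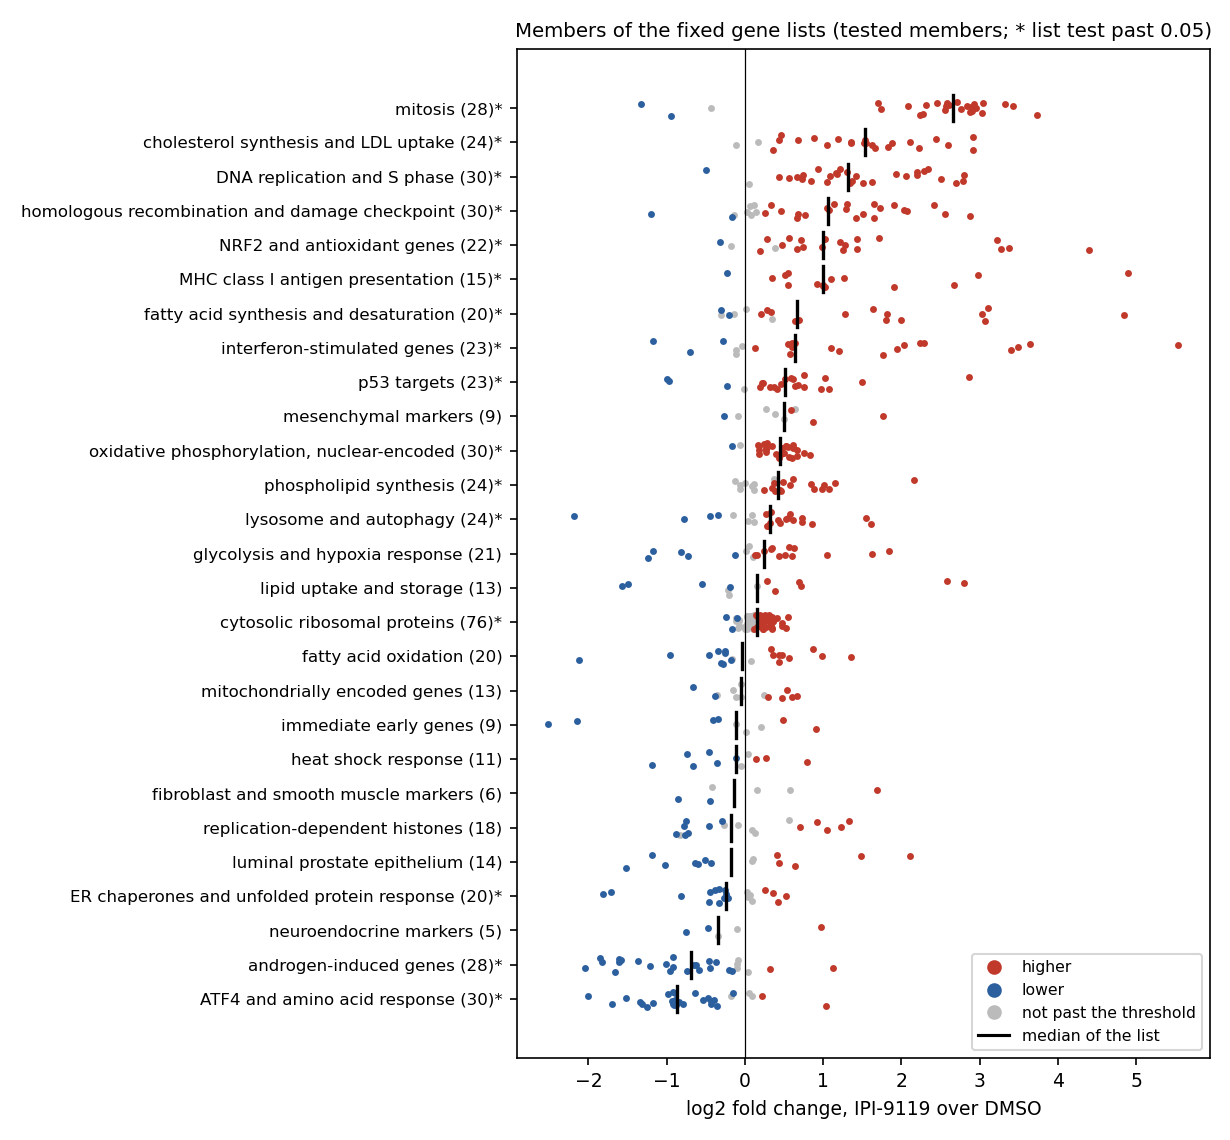
Log2 fold change (IPI-9119 over DMSO, x axis) of each tested member of the 27 gene lists with at least 4 tested members, with the number tested in parentheses and the list median as a black bar. Red points were higher, blue points lower and grey points not past the threshold. An asterisk marks the 16 lists past the list test with a preset correlation, of which 6 hold with an estimated correlation. Splits of the libraries that mix the groups gave 11 to 16 lists past the same preset test.

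Among the genes of fatty acid synthesis and desaturation, SCD, ELOVL6 and ACSL4 rose and ELOVL7 fell. SCD, the stearoyl-CoA desaturase (ENSG00000099194, chromosome 10, 100347124 to 100364834, plus strand), rose from 17771 ± 757 to 149292 ± 8810.2 normalised counts (SD, n = 3), 8.40-fold (SE of the log2 fold change 0.051, adjusted p 2.2e-14). ELOVL6, a fatty acid elongase, rose from 25.6 ± 4.95 to 757 ± 41.2, a log2 fold change of 4.84. ACSL4, an acyl-CoA synthetase, rose by a log2 fold change of 3.11, while the elongase ELOVL7 fell (-0.31, and -0.59 after the length and GC correction). Of 20 tested genes of fatty acid synthesis and desaturation, 14 rose, 2 fell and 4 did not pass (median log2 fold change 0.67). The list test (camera) gave an adjusted p of 2.3e-05, against adjusted p = 0.158 with an estimated correlation.

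Sterol synthesis genes rose together. HMGCS1, which makes HMG-CoA, rose from 1725.8 ± 50.92 to 13041.3 ± 392.4 normalised counts (SD, n = 3), a log2 fold change of 2.92 (SE 0.046, adjusted p 2.0e-14). INSIG1, a sterol-responsive regulator of the pathway, rose from 5303 ± 175 to 40015 ± 1338, and the sterol oxidase MSMO1 rose from 2257 ± 119 to 13612 ± 510.2. Of 24 tested genes of cholesterol synthesis and LDL uptake, 22 rose, 0 fell and 2 did not pass, and 23 rose when adjusted over the list alone. Their median log2 fold change was 1.53 (camera, adjusted p 1.1e-14; adjusted p = 0.0532 with an estimated correlation).

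**Figure D2:**
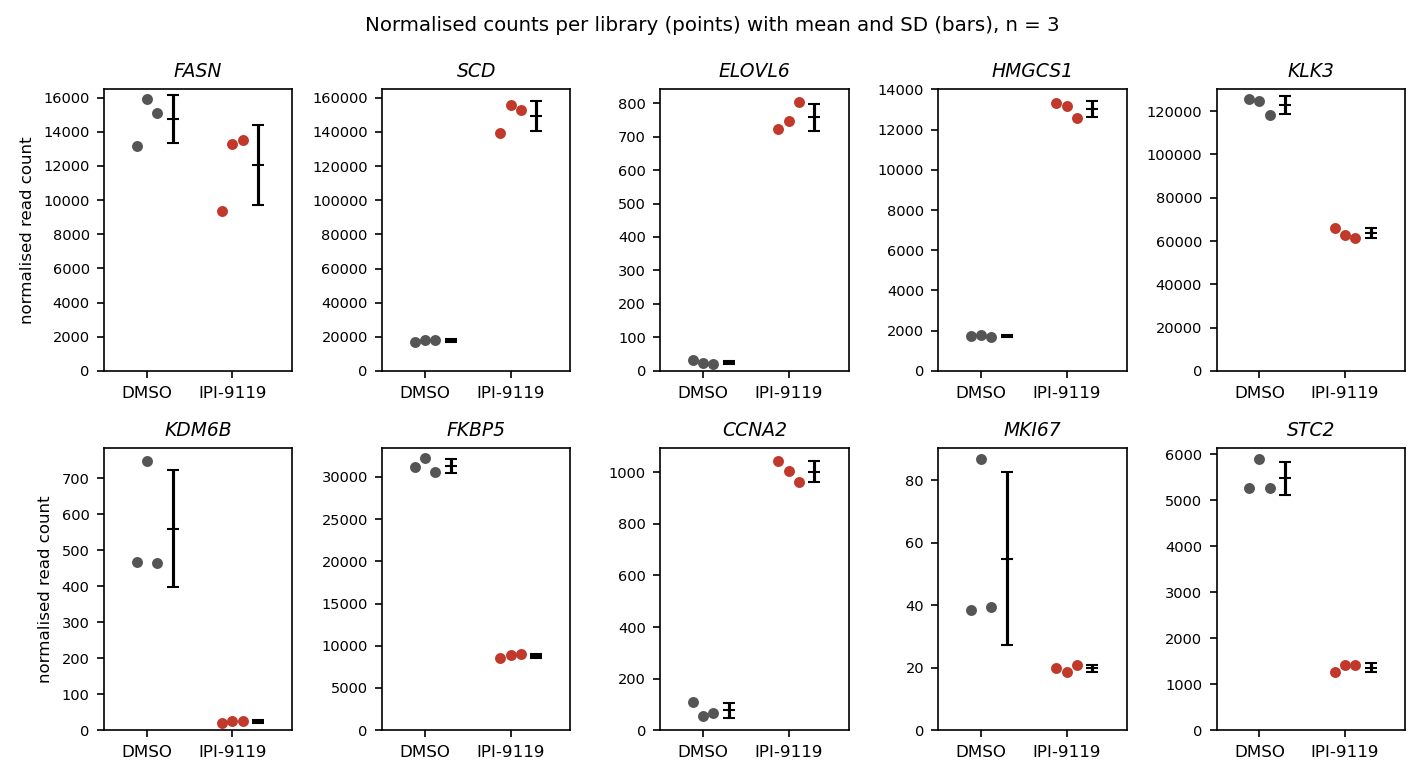
Normalised read counts (y axis, linear) of 10 named genes in each of the 3 DMSO and 3 IPI-9119 libraries (points), with mean and SD (bars). The groups overlap for FASN and are separate for the other genes.

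Phospholipid synthesis genes also rose, 16 of 24 with 0 lower and 8 not past (median 0.42; camera, adjusted p 1.2e-05; adjusted p = 0.0395 with an estimated correlation). LPIN1, a phosphatidate phosphatase, rose by a log2 fold change of 2.17, and the acyltransferases LPCAT1 and AGPAT5 rose by 1.16 and 1.07. Fatty acid oxidation genes went both ways, with 9 higher, 9 lower and 2 not past of 20. CPT1A, which starts mitochondrial fatty acid import, fell from 1732 ± 297 to 398 ± 54.9 normalised counts (SD, n = 3; log2 fold change -2.12), while the thiolase ACAA2 (1.36) and the dehydrogenase HADH (0.99) rose. That list was not past the threshold (camera, adjusted p 0.733), and its median (-0.042) had the opposite sign to its mean and test direction. For lipid uptake and storage 6 rose, 4 fell and 3 of 13 did not pass (median 0.16; camera, adjusted p 0.444). Lipoprotein lipase LPL (2.80) and the acyl-CoA synthetase SLC27A2 (2.58) rose, and the lipid droplet gene PLIN4 fell (-1.57, and -0.93 after the length and GC correction).

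Androgen-induced genes were lower. KLK3, which encodes prostate-specific antigen (ENSG00000142515, chromosome 19, 50854915 to 50860764, plus strand), fell from 122882 ± 4093 to 63576 ± 2314 normalised counts (SD, n = 3), a log2 fold change of -0.95 (SE 0.044, adjusted p 3.7e-10). The transcription factor MAF (-2.05), the kallikrein KLK4 (-1.85) and the cochaperone FKBP5 (-1.83) also fell. Of 28 androgen-induced genes, 2 rose, 22 fell and 4 did not pass, and 23 fell when adjusted over the list alone (median -0.69). The calcium channel gene TRPM8 was among those that rose (1.13). The list test gave an adjusted p of 1.1e-08 (camera; adjusted p = 0.0532 with an estimated correlation). Only 2 androgen-repressed genes were tested, too few for a list test. MET rose (0.99, adjusted p 0.0308) and lost its call without DMSO replicate 1 (adjusted p 0.0735) or 3 (0.0672), or IPI-9119 replicate 2 (0.129) or 3 (0.127).

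Markers of lineage and of other cell types showed no list past the threshold. For luminal prostate epithelium 5 of 14 genes rose, 7 fell and 2 did not pass (median -0.18; camera, adjusted p 0.311). The secreted protein gene MSMB (2.11) and the keratin gene KRT19 (1.48) rose, and the transcription factor GATA2 fell (-1.51). Of 5 neuroendocrine markers 1 rose, 2 fell and 2 did not pass (median -0.34; camera, adjusted p 0.733), with ENO2 higher (0.98) and SCG2 lower (-0.75). Mesenchymal markers gave 3 higher, 1 lower and 5 not past of 9 (median 0.50; camera, adjusted p 0.270), with LOX (0.88) and VIM (0.59) higher. Fibroblast and smooth muscle markers gave 1 higher, 2 lower and 3 not past of 6 (median -0.14; camera, adjusted p 0.923). The list of leukocyte and endothelial markers and that of basal epithelial markers each had 2 tested genes and none past the threshold. KDR had a log2 fold change of -1.62 (adjusted p 0.188, but -2.63 and 0.0138 without IPI-9119 replicate 2, and -0.31 and 0.565 without IPI-9119 replicate 3), and ITGB4 one of 0.51 (adjusted p 0.343, and 0.0185 after the length and GC correction).

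Mitotic genes were among the most increased groups. CCNA2, which encodes cyclin A2, rose from 77.8 ± 29.1 to 1003 ± 40.7 normalised counts (SD, n = 3), a log2 fold change of 3.73 (SE 0.21, adjusted p 2.7e-07). BIRC5, encoding survivin, rose from 228 ± 16.8 to 2461 ± 219 and HMMR, a spindle-associated protein gene, from 184 ± 9.62 to 1844 ± 27.3. Of 28 mitosis genes, 25 rose, 2 fell and 1 did not pass, and 3 fell when adjusted over the list alone. Their median log2 fold change was 2.66 (camera, adjusted p 1.1e-14; 0.0212 with an estimated correlation). MKI67, which encodes the proliferation marker Ki-67, went the other way. It fell from 54.9 ± 27.6 to 19.8 ± 1.19 normalised counts (SD, n = 3), a log2 fold change of -1.32 (SE 0.31, adjusted p 0.00175), and DMSO replicate 2 held 86.8 counts against 38.4 and 39.5 in the other DMSO libraries. After a correction for transcript length and GC content the value for MKI67 was -0.94 (adjusted p 0.00865). The mitosis genes that did not rise, MKI67 among them, were the longest of the list. Their exonic lengths were 9444 to 12807 nt, against at most 6576 nt for those that rose.

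S phase genes rose as well, with 28 of 30 higher, 1 lower and 1 not past (median 1.32; camera, adjusted p 8.0e-13; 0.0212 with an estimated correlation). CDC45, needed to start replication forks, rose by a log2 fold change of 2.81, thymidylate synthase TYMS by 2.79 and the ribonucleotide reductase gene RRM2 by 2.70. CHAF1A fell (-0.50), a call lost without DMSO replicate 2 (-0.35, adjusted p 0.0717). Homologous recombination and damage checkpoint genes gave 22 higher, 2 lower and 6 not past of 30 (median 1.07; camera, adjusted p 1.6e-06; adjusted p = 0.0532 with an estimated correlation). The DNA polymerase gene POLQ (2.88), the helicase gene BRIP1 (2.55) and the exonuclease gene EXO1 (2.42) rose, and RAD50 fell (-1.20). Of 23 p53 targets 19 rose, 3 fell and 1 did not pass (median 0.51; camera, adjusted p 0.00105; adjusted p = 0.158 with an estimated correlation). The death receptor gene FAS (2.87) and the cell cycle inhibitor gene CDKN1A (1.08) rose, as did TP53INP1, from 2232 ± 51.6 to 6333 ± 250.3 normalised counts (SD, n = 3). The cytokine gene GDF15 fell from 28868 ± 1209 to 14458 ± 160.1. Replication-dependent histones, with 5 higher, 7 lower and 6 not past of 18, were not past the threshold as a list (median -0.18; camera, adjusted p 0.729). H2BC11 (1.34) and H1-2 (1.23) rose, and H4C14 fell (-0.87).

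Genes of the ATF4 and amino acid response fell, 25 of 30 with 2 higher and 3 not past. STC2, a secreted glycoprotein gene, fell from 5469.6 ± 367 to 1360.4 ± 90.1 normalised counts (SD, n = 3), a log2 fold change of -2.01 (SE 0.062, adjusted p 9.2e-12). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell from 16373 ± 20.4 to 5039 ± 51.3 and CTH, of cysteine synthesis, from 3997 ± 227 to 1399 ± 67.6, while the stress transcription factor ATF3 rose (1.04). The list median was -0.86 (camera, adjusted p 4.0e-10; 0.0212 with an estimated correlation). ER chaperones and unfolded protein response genes gave 4 higher, 12 lower and 4 not past of 20 (median -0.24), with the sensor gene ERN1 (-1.82), the ubiquitin ligase gene SYVN1 (-1.72) and XBP1 (-0.82) lower and SDF2L1 higher (0.53). That list was close to the threshold (camera, adjusted p 0.0490; adjusted p = 0.158 with an estimated correlation). Its call was lost without DMSO replicate 1 (adjusted p 0.0607), IPI-9119 replicate 2 (0.0649) or IPI-9119 replicate 3 (0.0600), and with a pseudocount of 8 (0.0503), a mean of at least 50 (0.0732) or no trend (0.0881).

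NRF2 and antioxidant genes rose, 19 of 22 with 1 lower and 2 not past (median 1.00; camera, adjusted p 3.5e-08; 0.0212 with an estimated correlation). The aldo-keto reductase genes AKR1C1, AKR1B10 and AKR1C2 had 1, 5 and 6 reads over all DMSO libraries and 70, 60 and 62 over the IPI-9119 libraries. AKR1C1 and AKR1C2 are close paralogs, so their separate levels are uncertain, and the level of AKR1B10 rests on few reads. The glutathione synthesis gene GCLC fell (-0.32). Heat shock genes, with 3 higher, 6 lower and 2 not past of 11, gave no list call (median -0.12; camera, adjusted p 0.224). The adjusted p was 0.378 with an estimated correlation and 0.0283 after the length and GC correction. BAG3 (-1.18) and HSP90AA1 (-0.74) fell, and HSPB1 rose (0.79). Immediate early genes gave 2 higher, 4 lower and 3 not past of 9 (median -0.11; camera, adjusted p 0.352), with NR4A1 (-2.51) and KLF4 (-2.14) lower. Glycolysis and hypoxia response genes gave 13 higher, 5 lower and 3 not past of 21 (median 0.25). The prolyl hydroxylase gene EGLN3 (1.85) and aldolase ALDOC (1.62) were higher and ANKRD37 lower (-1.23). Their list was not past the threshold (camera, adjusted p 0.0506, and adjusted p = 0.488 with an estimated correlation). That list passed without DMSO replicate 3 (adjusted p 0.0351), with a pseudocount of 0.5 (0.0499), without the filter on low genes (0.04996) and after the length and GC correction (0.0283).

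Interferon-stimulated genes rose from low levels, 17 of 23 with 3 lower and 3 not past (median 0.65; camera, adjusted p 0.00127; adjusted p = 0.0532 with an estimated correlation). OASL had 0 reads in the DMSO libraries and 48.3 ± 20.2 normalised counts (SD, n = 3) with IPI-9119, at least 17.5-fold higher against a floor of 3 reads per library. With OASL at that bound, which still lies above the list median, the median is 0.65 by construction. IFIT3, with 8 reads over the DMSO libraries, rose from 2.45 ± 0.536 to 41.9 ± 5.002 normalised counts (SD, n = 3), and IFI44 rose by a log2 fold change of 3.50. The antiviral GTPase gene MX1 fell (-1.17). Of 15 genes of MHC class I antigen presentation 14 rose and 1 fell (median 1.00; camera, adjusted p 9.7e-06; adjusted p = 0.0395 with an estimated correlation). The immunoproteasome gene PSMB8 rose from 13.4 ± 4.39 to 109.8 ± 14.7 normalised counts (SD, n = 3), PSMB9 went from 4 reads over the DMSO libraries to 136, and NLRC5, a regulator of class I genes, from 11 to 80. TAPBP fell (-0.23, adjusted p 0.0399), a call lost without DMSO replicate 1 (adjusted p 0.0829) or 2 (0.144) or IPI-9119 replicate 1 (0.151), and after the length and GC correction (0.468). Floors cover counting error only.

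Nuclear genes of oxidative phosphorylation were modestly higher, 28 of 30 with 1 lower and 1 not past (median 0.45; camera, adjusted p 1.0e-07; adjusted p = 0.428 with an estimated correlation). NDUFA1 (0.83), NDUFB3 (0.75) and ATP5MC1 (0.67) rose. NDUFB10 fell (-0.16, adjusted p 0.0163), a call lost without DMSO replicate 1 (adjusted p 0.0718) or 3 (0.0678) or IPI-9119 replicate 2 (0.0680) or 3 (0.0691). After the length and GC correction it was -0.32. Mitochondrially encoded genes took 1.41% ± 0.149 of reads with DMSO and 1.80% ± 0.247 with IPI-9119 (SD, n = 3). Of these 13 genes 5 rose, 2 fell and 6 did not pass, with MT-ND3 (0.67) and MT-CO3 (0.60) higher and MT-ND6 lower (-0.67). The list was not past the threshold (camera, adjusted p 0.509), and its median (-0.042) had the opposite sign to its mean and test direction. Cytosolic ribosomal protein genes gave 41 higher, 3 lower and 32 not past of 76, with RPS12 (0.56) and RPLP0 (0.52) higher and RPL12 lower (-0.24, and -0.39 after the length and GC correction). Their median was 0.16 (camera, adjusted p 1.4e-04; adjusted p = 0.719 with an estimated correlation), and the call was lost after the length and GC correction (adjusted p 0.235). Of 24 lysosome and autophagy genes 16 rose, 4 fell and 4 did not pass, and 5 fell when adjusted over the list alone (median 0.33; camera, adjusted p 0.00382; adjusted p = 0.0926 with an estimated correlation). The kinase gene ULK1, which starts autophagy, fell (-2.18, and -1.30 after the length and GC correction), and the sterol carrier gene NPC2 (1.62) and the galactosidase gene GLA (1.55) rose.

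The largest rises among genes with a mean of at least 100 over all libraries included the iodothyronine deiodinases DIO1 (5.70) and DIO3 (5.68). DIO1 rose from 6.75 ± 2.36 to 390.1 ± 41.1 normalised counts (SD, n = 3). DIO1, DIO3 and BIRC3 had 22, 44 and 45 reads over all DMSO libraries, and with a pseudocount of 8 their log2 fold changes were 4.76, 5.01 and 4.32. BIRC3 (4.88), an inhibitor of apoptosis, ID3 (3.94), an inhibitor of bHLH factors, TXNIP (3.88), a thioredoxin-interacting protein, CLEC7A (3.84) and AGR2 (3.83) also rose, with adjusted p-values up to 1.7e-06 for DIO3. Among the largest falls, KDM6B, a histone demethylase, fell from 559 ± 162 to 23.5 ± 3.96 normalised counts (SD, n = 3), a log2 fold change of -4.49 (SE 0.19, adjusted p 2.0e-10). The splicing factor SRRM2 (-4.03), TNRC18 (-4.00), the acetyltransferase CREBBP (-3.91), ZMIZ1 (-3.82), HCFC1 (-3.77) and BCL9L (-3.71) fell too. After the length and GC correction the log2 fold changes were smaller, at -3.75 for KDM6B, -3.25 for SRRM2 and -2.35 for TNRC18. They were -3.10 for CREBBP, -3.04 for ZMIZ1, -2.90 for HCFC1 and -2.64 for BCL9L. These genes have large exonic lengths (7258 to 15492 nt, all annotated exons merged) and a high GC content (55.8% to 67.1%).

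Genes with a large exonic length and a high GC content were lower with IPI-9119 as a class. Across 12105 protein-coding genes, which are not independent replicates, log2 fold change had a Spearman rho of -0.23 with exonic length and -0.18 with GC content. The 403 genes in the top quartile of both had a median log2 fold change of -0.76, and 68.2% of them were lower. The 387 genes in the bottom quartile of both had a median of 0.23. The difference between these classes, as a log2 deviation per library, was 0.36, 0.64 and 0.51 in the DMSO libraries and -0.71, -0.41 and -0.39 in the IPI-9119 libraries. Of 9039 calls with a corrected value, 7466 kept their call and direction after the length and GC correction. Of the 16 lists past the threshold, 15 kept their call after it, and 6 held with an estimated correlation.

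**Figure D3:**
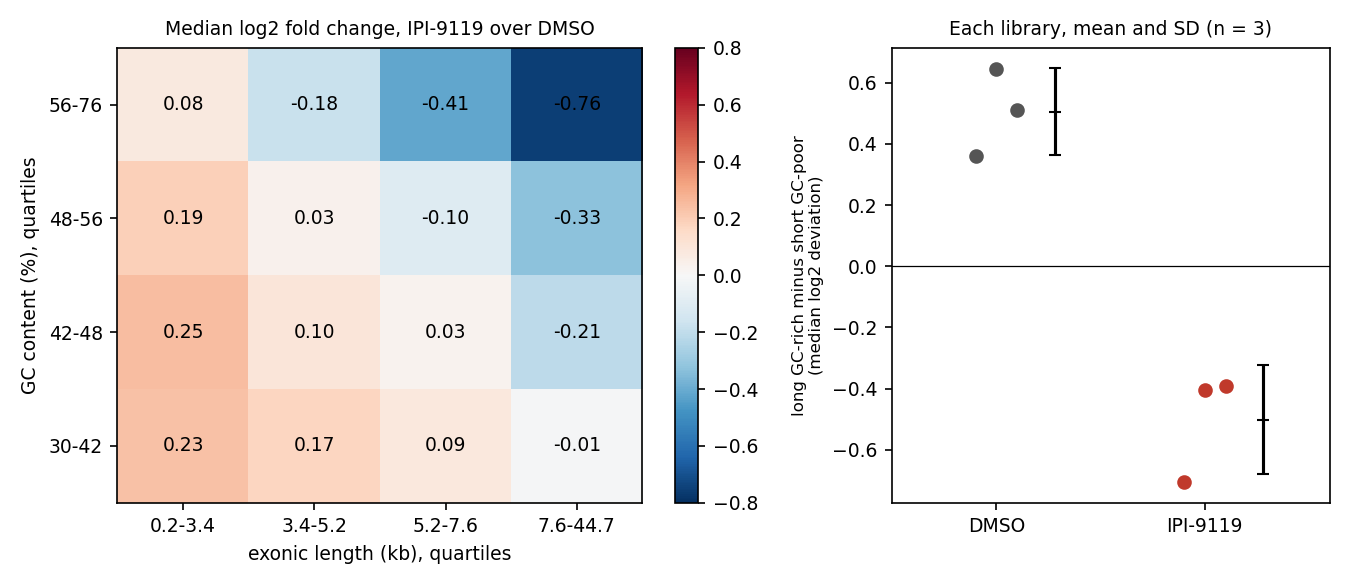
Median log2 fold change of protein-coding genes by quartile of exonic length (x axis, kb) and GC content (y axis, percent), and the difference between the long GC-rich and the short GC-poor class in each library with mean and SD (n = 3). The long GC-rich class has a median of -0.76 and the short GC-poor class 0.23.

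For each gene named as risen or fallen, the 3 IPI-9119 libraries lay on the same side of all 3 DMSO libraries, except for TAPBP. The strand setting of the counting was not given in the sources used here. The spans, from gene start to gene end, of SLC27A2, PLIN4, GATA2, ENO2, LOX, VIM, ITGB4, CCNA2, TYMS, CHAF1A, FAS, TP53INP1, PCK2, SYVN1, GCLC, HSP90AA1, EGLN3, ALDOC, ANKRD37, PSMB8, NDUFA1, NDUFB3, ATP5MC1, MT-CO3, NPC2, SRRM2, TNRC18, IFIT3 and PSMB9 overlap that of another tested gene in GENCODE 29. Overlap of their exons was not examined, so their values may be uncertain where exons are shared. Member counts adjusted over the list alone were those given for all genes tested, except in the lists where another count stands beside them, and over all lists they came to 477 changed genes against 473 of 589.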

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

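The length and GC correction was an alternative chosen after the data were seen. Under the alternatives run, genes called higher ranged from 3930 to 4797 (4522 as reported) and genes called lower from 4022 to 4906 (4539). Of 117 named genes, 104 kept their direction and side of the threshold under every alternative run on them. At least 2-fold higher genes fell to 677 with a mean of at least 50, where fewer genes were tested. The list count moved from 16 to 6 with an estimated correlation and to 27 with the mixed fry test, which asks another question. FASN was reversed by the length and GC correction (0.84, adjusted p 2.1e-08), and ITGA5 too (from -0.26 to 0.095, adjusted p 0.354). ITGA5 also lost its call without DMSO replicate 2 (adjusted p 0.115) or 3 (0.0815) or IPI-9119 replicate 1 (0.106) or 2 (0.0749). The cause was not tested beyond what is given for FASN among the other observations. Leaving out each library in turn gave FASN values from -0.40 to -0.13, with adjusted p-values from 0.0225, without IPI-9119 replicate 3, to 0.298.

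With a replicate block, FASN stayed at -0.31 with an adjusted p of 2.7e-05, and 4797 genes were higher and 4799 lower. The block also put KDR (adjusted p 0.0312) and the glycolysis and hypoxia list (0.0433) past the threshold, and changed the call of no other named gene or list. Correlations of deviations between libraries of the same number were 0.14, 0.063 and 0.0044, and DMSO replicate 2 correlated best with IPI-9119 replicate 3 (0.099), so the numbers are not taken to pair the libraries. TMM and quantile scaling moved the median log2 fold change of all genes to -0.0041 and 0.020, and the share of calls that were higher from 49.9% to 49.3% and 52.4%. Depth limits genes near the floor of 3 reads, such as OASL, IFIT3, PSMB9, NLRC5, KDR and the aldo-keto reductases, whose fold changes depend on the pseudocount.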

Other observations

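The symbol-stem groups, the test within the mitosis and S phase lists, the length and GC correction of those lists and the comparison of FASN with matched genes were chosen after the result was seen. Protein-coding genes grouped by the stem of their symbol gave 144 groups of at least 10 genes, of which 27 passed camera and 18 also did so after the length and GC correction. With an estimated correlation the adjusted p was 0.731 for each group named here, so none passed. Most groups had this same value, also those with little change such as ABHD genes (median 0.058). That version, with its 4 residual degrees of freedom, therefore cannot tell the groups apart. Mitochondrial ribosomal MRPL genes had 35 higher and 0 lower of 49 (median log2 fold change 0.27, adjusted p 0.00024, and 0.0486 after the correction). Cytochrome P450 CYP genes had 13 higher and 0 lower of 17 (median 0.95, adjusted p 0.00521). Zinc finger ZNF genes had 197 lower and 44 higher of 437 (median -0.26, adjusted p 0.00136), and histone demethylase KDM genes 13 lower and 0 higher of 18 (median -0.54, adjusted p 0.00166). RNA-binding RBM genes had 22 lower and 2 higher of 34 (median -0.30, adjusted p 0.00164).

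Transcripts of genes with a large exonic length and a high GC content were lower with IPI-9119. Lower depth of those libraries is argued against, since the median of 403 such genes stayed at -0.77 after thinning all libraries to the smallest. Less transcription along long genes is argued against by a partial correlation of 0.0031 with genomic span at fixed exonic length and GC content. A loss of long transcripts whatever their function may contribute and stays open. Within the mitosis and S phase lists rho with exonic length was -0.51 (58 genes, permutation p 5e-05; -0.46 without the 2 longest). Among 531 other list genes it was -0.073. Genes are not independent replicates, so the permutation p does not measure the spread between libraries. The pooled lists also differ in median exonic length (mitosis 3873 nt, S phase 4238 nt) and in median log2 fold change (2.66 and 1.32). A difference in RNA quality or library batch cannot be told apart from the treatment, whose own effect on long transcripts was untested.

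Mitosis and S phase transcripts were higher, with a median log2 fold change of 2.20 over 58 genes. The length and GC trend as the whole cause is argued against by a median of 2.01 after the correction. The lowest median under TMM and quantile scaling was 2.20, so the rise did not hang on the choice among these scalings. They hardly moved the median of all genes (to -0.0041 and 0.020), so a shift common to all genes was not tested. A difference in culture density or growth state between the dishes, or an effect of the inhibitor, could produce the same values and was not tested.

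FASN was not past the threshold, yet rose by 0.84 after the length and GC correction. A rise hidden by the trend is a candidate explanation that stays open, because the tables disagree. Among the 200 genes nearest to it in length (9364 nt) and GC content (65.3%), FASN stood at the 65.5 percentile, inside their quartiles of -1.65 and -0.19 around a median of -0.75. The corrected value thus depends on the fitted surface, and a rise of FASN is not established here.

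The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split alone gave 4522 higher and 4539 lower genes, with 1143 and 1338 at least 2-fold. Thus 1 split gave as many in each case, and the highest count of any other split was 0. In every other split the difference between treatments adds to the spread within the groups, which suppresses gene calls. The counts of 0 are therefore no support for the real grouping. For gene lists past camera with the preset correlation, 2 splits gave as many as the real 16, and the other splits gave 11 to 16. Those splits mix the groups, so each still holds part of the group difference.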
